A study of Homo sapiens with 10 samples.

How the data were processed

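Gene expression was measured in cultured normal human fibroblasts, a cell-bank strain at passage 20. Per the labels' protocols, 500000 cells on a 60 mm plate received 800 ng of the small RNA fraction (up to 200 bp) of the same kind of cell, or the transfection mix with 0 ng of RNA (mock). The medium was changed at 24 h and total RNA was taken at 38 h. Each group had 5 biological repeats according to the series' design text, and 0.3 µg of RNA per repeat was labelled with Cy3 and put on 1 of 10 one-colour Agilent whole human genome arrays.

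Per the file headers, each array's signal intensity columns came from Agilent Feature Extraction 10.5.1.1 (10.5 per the labels), which subtracted background and removed spatial trends within the array but did not scale arrays to each other. The other columns used were the flags for spots well above background, saturated or uneven, 0 or 1 per the file headers, and the control type. Each array held 45015 spots, of which 43376 were not controls and carried 41000 probes. Probe coordinates in the files are on the hg18 build. Probes were named through their RefSeq accession in the reference list of genes (25398 probes), through a current symbol (2510) or an older symbol (789). The remaining 12303 probes kept the file's name. The reference table names the assembly GRCh38.p14, so none of its coordinates were used. The probes covered 30142 gene names.

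The deposited whole-series table is on the log2 scale, as found by setting its columns against the scanner values, since neither the authors' notes nor a header states its scale. Of 34900 values for genes with 1 probe, 99.8% equalled the log2 processed signal plus 1 constant per array within 0.01. For genes with several probes, 99% of 19670 values equalled the mean of the probes detected on that array. The table was not centred per gene. Each array's 75th percentile of the scanner's log2 signal over all probes, plus the array's constant, lay between 10.49 and 10.57. Of its 5773 genes, 4811 had a value on every array. Its column medians were 7.62, 7.45, 7.57, 7.52 and 7.5 for the transfected replicates 1 to 5, and 8.29, 8.22, 7.6, 7.56 and 7.64 for the mock replicates. How the 5773 genes were chosen stays unknown.

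From the scanner files, the log2 processed signal of non-control spots was taken without uneven spots (102 probes lost a value on at least 1 array), spots of 1 probe were averaged, and each array's 75th percentile was subtracted. A gene was represented by its probe with the highest mean signal over the 10 arrays, and 22953 genes whose probe was well above background on at least 5 of the 10 arrays, whatever their group, were tested. Of 47 genes under the naming rule with several probes, 19 had probes that differed in sign. The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided; files read with version 1.17.8 of the data.table package) and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. This fit holds no block. Errors are standard errors of the fit with n = 5 arrays per group, and the number of arrays limits the precision. The 95% confidence interval of a log2 fold change reached 0.225 to each side for the median gene (1.17-fold), a width that includes the difference between scan days, against 0.125 with scan day as a block and 0.14 with the replicate block.

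In total 31 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, with an estimated correlation beside it, and with fry. The lists held interferon-stimulated and RNA-sensing genes; inflammatory cytokines and NF-kB targets; G1/S and DNA replication genes; G2/M and mitosis genes; replication-dependent histones; p53 targets; collagens and extracellular matrix; myofibroblast and actin cytoskeleton genes; matrix proteases and inhibitors. Textbook targets of let-7, miR-21, miR-29, miR-15/16, miR-17-92, miR-24, miR-143 with miR-145, miR-34, and miR-221 with miR-222 made up 9 more. The others were small RNA biogenesis and silencing factors, ribosome biogenesis and snoRNP genes, integrated stress and unfolded protein response genes, cholesterol and fatty acid synthesis, immediate early genes, heat shock genes, glycolysis and hypoxia genes, markers of epithelial, endothelial, leukocyte and melanocyte cells, ZNF zinc finger genes, and ribosomal proteins without Y-linked members. A list was tested with at least 5 measured members, and members with an adjusted p under the threshold were counted over all genes tested and adjusted over the list alone. A list's shift is its median log2 fold change minus that of the other genes.

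The genes named were the 12 with the largest change per direction among those past the threshold with a symbol and a probe well above background on all 10 arrays. Where fewer than 6 passed in a direction, the 6 with the smallest p were named as not past the threshold. From each list up to 4 members with the smallest p were allowed, of which the text names the first 4 for lists past the threshold and the first few for the others, a narrowing made after the data were examined. Genes of the scan-day fits were named by size of change in the same way, though only some of those for the difference between the days are given. For the interaction the genes were those already named, not those with the largest interaction, and PBK was added after its values were seen. The groups, the test, the filter, the lists, the naming rule and all alternatives other than those listed as added were fixed before the data were examined.

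The file headers place the arrays on 4 slides and 2 scan days. Scan day 1 held replicates 1 and 2 of each group, and scan day 2 held replicates 3, 4 and 5. Slide 1 held transfected replicate 1 with mock replicates 1 and 2, slide 2 transfected replicate 2, slide 3 transfected replicate 3 with mock replicates 3, 4 and 5, and slide 4 transfected replicates 4 and 5. Same-numbered arrays deviated together from their group means, with correlations across genes of 0.59, 0.53, 0.61, 0.52 and 0.53. Within a scan day these correlations were 0, 0, 0.02, -0.04 and 0.07, so the pairing came from the scan day. The main fit did not treat the numbers as pairs, and the replicate block was an alternative.

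The other settings tried were normexp background correction (offset 50) with 75th percentile or quantile normalization, quantile normalization of the processed signal, scaling by the median, no scaling, no filter on dim probes, a filter for all 10 arrays, the mean of a gene's probes, each probe tested alone, the deposited table, slide as a block and as a random block (duplicateCorrelation), the replicate block, an intensity trend with a robust prior, leaving out each replicate in turn, an estimated correlation for lists, and stricter thresholds (adjusted p under 0.01, or at least 1.5-fold). Alternatives chosen after seeing the data were scan day as a block, a correction of each array for probe base composition (a regression of its log2 values on the probes' A, C and G fractions, their squares and products), this correction with the scan-day block or the replicate block, and each scan day alone. For pairs of probes of 1 gene, the correlation that fully shared changes would reach was taken from the share of the variance of the changes that their squared standard errors leave, as the geometric mean over both probes. The planned test of miRNA seed matches was left out, since the reference holds no transcript sequences.

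The fits were tested on simulated data with 22953 genes, of which 200 were changed, 50 at each fold. The fit without a block recovered 12% of changes of 1.2-fold, 58% of 1.5-fold, 74% of 2-fold and 78% of 3-fold, with 2 false calls. With a scan-day block these shares were 50%, 88%, 90% and 94%, with 15 false calls, and with a replicate block 24%, 78%, 82% and 92%, with 10. A simulated shift of 0.3 in the collagen list was found as 0.31, and 1 other list was called, the miR-29 targets, which holds many of the same collagens. The simulated noise was independent between genes and between arrays, without slide or probe composition effects. In the real arrays the correlation within slides was 0.69 in the fit without a block. Each slide lay within 1 scan day, so this value also holds the difference between scan days, which the simulation did include. The part due to slides alone was not measured, so these shares and false calls may not carry over to the real arrays.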

Results

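The data were 10 arrays of cultured fibroblasts, 5 of small RNA-transfected and 5 of mock-transfected cells. Between 64.2% and 80.2% of the 41000 probes were well above background per array, and no spot was saturated. The 75th percentile of the processed signal lay between 944 and 1500 intensity units. Scan day set the arrays apart more than transfection did. The median correlation between arrays was 0.997 within a group and day, 0.996 between groups within a day and 0.985 between days. The first principal component held 60.3% of the variance and parted the scan days. The second held 13.4% and parted the groups on scan day 1, whereas on scan day 2 transfected replicate 3 lay near the mock arrays of its slide.

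**Figure D1:**
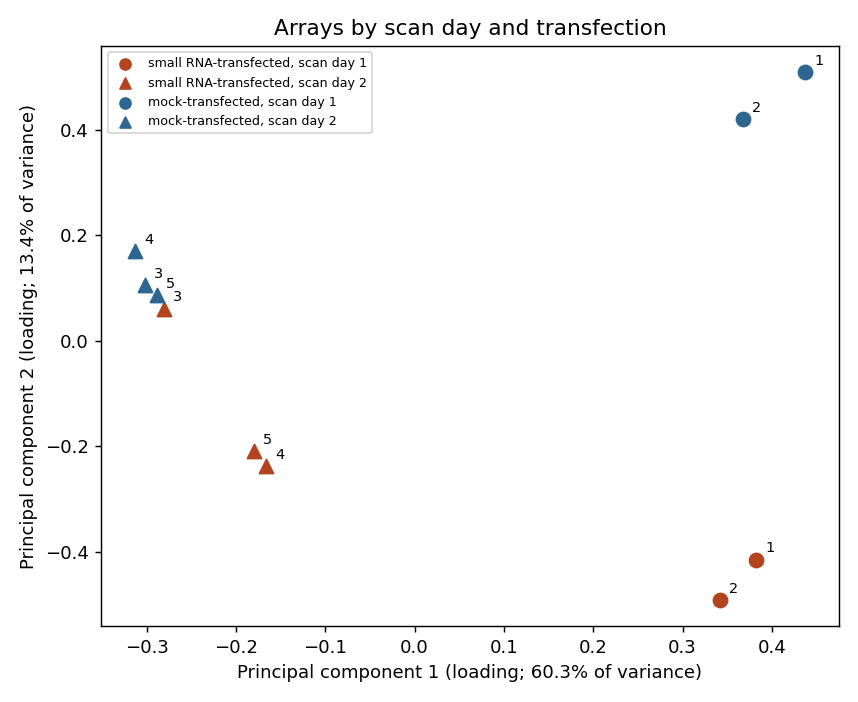
Loadings of the 10 arrays on principal component 1 (60.3% of variance) and component 2 (13.4%), coloured by group, shaped by scan day and numbered by replicate. The scan days part along component 1, and transfected replicate 3 (0.061 on component 2) sits beside mock replicate 5 (0.0871).

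The comparison asked which messenger RNAs respond when small RNAs of the same kind of cell, microRNAs among them, are transfected. Small RNA levels after transfection are not given, so a rise was not shown. Mock cells received 0 ng of RNA, so an effect of microRNAs cannot be told apart from one of added RNA as such. The genes lowest in the transfected cells by rank were NPBWR1, a receptor for neuropeptides B and W, CHGA, a protein of neuroendocrine secretory granules, RTBDN, a flavin-binding protein of the retina, NKX2-5, a transcription factor of the developing heart, SSX5, a cancer-testis antigen, and the long non-coding RNA gene LINC00304. Those highest by rank were CDO1, which oxidises cysteine, GEN1, a resolvase of DNA recombination junctions, VPS50, of an endosome recycling complex, TSPAN11, a tetraspanin, ETFBKMT, a mitochondrial methyltransferase, and PABIR3. None of them passed the threshold.

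In limma, 0 of 22953 genes passed the threshold (smallest adjusted p = 0.0982). At an unadjusted p under 0.05 there were 2097 genes, 197 higher and 1900 lower, where chance alone gives 1148. This split moved with the scaling, to 982 of 2390 higher with median scaling, 657 of 2032 with quantile normalization, 533 of 632 without scaling and 741 of 1579 with composition correction. NPBWR1 had a log2 fold change of -0.60 ± 0.09 (SE, n = 5 per group; probe on chromosome 8, 54015820 to 54015879, hg18), SSX5 of -0.55 ± 0.08, RTBDN of -0.49 ± 0.07, LINC00304 of -0.38 ± 0.05, NKX2-5 of -0.34 ± 0.05 (chromosome 5, 172591921 to 172591980) and CHGA of -0.31 ± 0.05 (chromosome 14, 92471071 to 92471130). Each of these 6 had an adjusted p of 0.0982, lower in 5 of 5 transfected arrays than the mock mean. All 6 were lower on both scan days, NPBWR1 by -0.49 and -0.67 and NKX2-5 by -0.47 and -0.26. Genes picked by a small p over these same arrays tend to keep their side in each array and on both days. Such agreement among the genes named by rank therefore adds no support. With the scan-day block and a correction for probe base composition NPBWR1 was at -0.30, SSX5 at -0.49, RTBDN at -0.34 and NKX2-5 at -0.16, while LINC00304 (0.04) and CHGA (0.02) changed sign. On the higher side, ETFBKMT had 0.18 ± 0.05 (adjusted p = 0.169), CDO1 0.21 ± 0.06 (0.192), PABIR3 0.17 ± 0.05 (0.234), GEN1 0.17 ± 0.05 (0.264), TSPAN11 0.19 ± 0.06 (0.267) and VPS50 0.21 ± 0.07 (0.273), each in 5 of 5 transfected arrays. Another GEN1 probe, also well above background on 10 arrays, gave -0.197, and a dimmer one 0.034. The other PABIR3 probe gave 0.016, while the other VPS50 probes were all positive. With normexp background correction and the 75th percentile, where the median of all genes moved to -0.132, ETFBKMT (-0.34), CDO1 (-0.32), PABIR3 (-0.16) and GEN1 (-0.34) lay below that median and TSPAN11 (-0.073) and VPS50 (-0.024) above it. With normexp and quantile normalization all 6 stayed positive, from 0.14 (PABIR3) to 0.20 (VPS50). The 95% confidence interval lay within 1.5-fold for 17079 genes, or 74.4%.

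**Figure D2:**
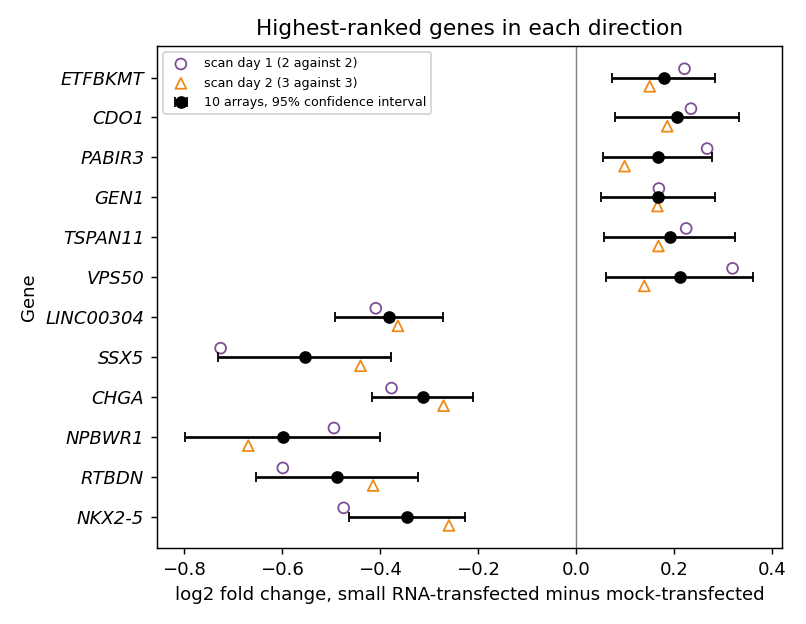
Log2 fold change (small RNA-transfected minus mock-transfected) of the 6 highest-ranked genes per direction, with the 95% confidence interval over 10 arrays and the value of each scan day as open symbols. The scan days share the sign for all 12 genes, which their choice by a small p over these same arrays favours. NPBWR1 (-0.60) and SSX5 (-0.55) lie furthest from 0, though a composition correction turned LINC00304 and CHGA positive. Normexp with the 75th percentile, not with quantile normalization, put ETFBKMT, CDO1, PABIR3 and GEN1 below the median gene.

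With scan day as a block, the 12 lower genes with the largest change past the threshold included AVP, which encodes vasopressin, the chemokine CCL19, the leukocyte receptor LILRB3, the adhesion molecule CEACAM1, the fatty acid elongase ELOVL3 and LCE4A of the cornified skin envelope. The muscle gene STAC3, the receptor genes MC5R and NPBWR1, the zinc finger gene ZNF205, LMNTD2 and DCANP1 complete the 12. Several of the 12 were dim, though well above background on all 10 arrays. Scaled mean log2 signals in transfected and mock arrays were -5.44 and -4.55 for LILRB3 and -5.5 and -4.81 for ELOVL3. They were -4.87 and -4.08 for CEACAM1 and -4.75 and -4.15 for CCL19. TLR3, a gene near background, had -5.2 and -5.5. AVP (-1.3 and -0.68), ZNF205 (1.0 and 1.63) and NPBWR1 (1.21 and 1.8) were the brightest of the 12. The glycine transporter gene SLC6A9, the transcription factor gene MSC, CCDC122 and RIPOR2 passed as higher. This fit was chosen after seeing the data and called 610 genes, 6 higher (1%) and 604 lower (99%), with 4324 at an unadjusted p under 0.05. AVP stood at -0.64 ± 0.08 (adjusted p = 0.0297), ELOVL3 at -0.69 ± 0.12 (0.0328), LILRB3 at -0.89 ± 0.18 (0.0406), CCL19 at -0.60 ± 0.12 (0.0445) and CEACAM1 at -0.79 ± 0.17 (0.0458), each lower in 5 of 5 transfected arrays. SLC6A9 stood at 0.26 ± 0.06 (adjusted p = 0.0451, higher in 4 of 5 arrays) and MSC at 0.14 ± 0.03 (0.0309, higher in 2 of 5 arrays than the mock mean of both days). The called genes had GC-rich probes, with a median of 55% G and C against 43.3% over all genes. The median log2 fold change was 0.04 for genes with probes of up to 35% GC and -0.29 for the 491 genes with probes above 65%. After correction for probe base composition 0 genes passed in limma with the scan-day block (smallest adjusted p = 0.0582, 4881 at an unadjusted p under 0.05, of which 3250 higher). AVP was then at -0.35, LILRB3 at -0.78, ELOVL3 at -0.64 and CCL19 at -0.48. With the replicate block 0 genes passed (smallest adjusted p = 0.0717, 3476 at an unadjusted p under 0.05). Within scan day 1 alone 0 passed, with 4758 at an unadjusted p under 0.05, and within scan day 2 alone 0, with 3199.

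**Figure D3:**
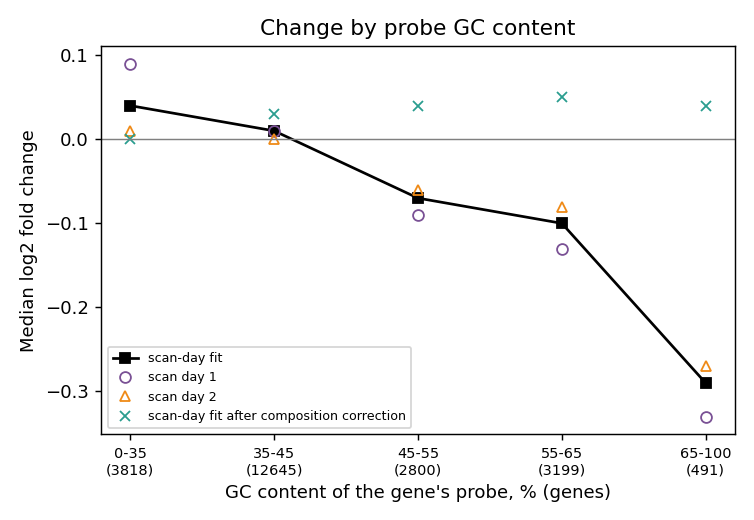
Median log2 fold change by GC content of the gene's probe, in 5 classes with the number of genes below each, for the scan-day fit, for each scan day and after composition correction. The line goes from 0.04 to -0.29, both days go down with GC content, and the corrected medians lie between 0 and 0.05.

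Textbook microRNA targets would be the genes to move down if added microRNAs acted on them. Among let-7 targets the death receptor FAS and the cell cycle phosphatase CDC25A ranked first, and among miR-15/16 and miR-34 targets the survival gene BCL2. SMAD4 and TGFBR2, parts of TGF-beta signalling, led the miR-17-92 list, and the estrogen receptor ESR1 led those of miR-221 and miR-222. None of the 9 target lists passed, and their medians lay above 0 in the fit without a block. Within scan day 2 alone the miR-29 (adjusted p = 0.0178) and miR-17-92 targets (0.0295) passed upward, though with an estimated correlation neither did (0.600 for both). The miR-17-92 targets had a median of 0.039 over 20 genes (camera adjusted p = 0.0723, list mean higher in 4 of 5 transfected arrays), with 0.070 on scan day 1 and 0.032 on scan day 2. The composition correction took this list to the lower side of the other genes by -0.012. The miR-21 targets had 0.054 (0.208, 3 of 5 arrays; 0.077 and 0.021 by day), the miR-29 targets 0.017 (0.216, 2 of 5; 0.0021 and 0.045) and the miR-24 targets 0.016 (0.208, 4 of 5; 0.094 and 0.010). The miR-221 and miR-222 targets had 0.043 (0.708, 2 of 5; 0.13 and 0.023). For let-7 targets the median was 0.013 and the mean -0.0028, with the test upward (0.262; 0.037 and 0.014 by day). The miR-143 and miR-145 list likewise had a median of 0.017 and a mean of -0.0026 (0.262; 0.00079 and 0.030). Median and mean also differed in sign, with the test upward, for miR-15/16 targets (0.017 and -0.020; 0.599; -0.024 and 0.017 by day) and miR-34 targets (0.014 and -0.028; 0.357; 0.0025 and 0.020). The list mean was lower in 2, 3, 5 and 4 of 5 transfected arrays for these last 4 lists.

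Among single targets BCL2 had the largest value, -0.66 ± 0.17 (adjusted p = 0.159, lower in 5 of 5 transfected arrays; -0.74 and -0.60 by day), but a dimmer probe of the gene gave 0.28. ESR1 had -0.36 ± 0.07 (adjusted p = 0.101, 5 of 5 arrays; 0.0333 with the scan-day block, 0.0930 with the replicate block). Without a block it was the only miR-221 and miR-222 target past the threshold adjusted over the list alone, with 0 over all genes tested. With the scan-day block 4 targets of this list passed adjusted over the list alone and 1 over all genes tested. The 4 did not share a direction, since ESR1 (-0.36) and BBC3 (-0.24) were lower and CDKN1C (0.17) was higher. After composition correction BBC3 turned to 0.14, and CDKN1C was at 0.14 too. After composition correction BCL2 was at -0.41, ESR1 at -0.19, MYCN at -0.066, TGFBR2 at 0.13, CDK4 at 0.18, CDK6 at 0.029 and MCM10 at -0.070. MYCN had -0.35 ± 0.13 (0.385, 5 of 5), FAS 0.15 ± 0.06 (0.459, 5 of 5), SMAD4 0.13 ± 0.06 (0.535, 5 of 5) and CDC25A -0.12 ± 0.06 (0.606, 5 of 5). TGFBR2 stood at 0.065, the cyclin-dependent kinase genes CDK4 at 0.081 and CDK6 at 0.10, MYC at 0.076 and the replication factor MCM10 at -0.11. With the mean of a gene's probes TGFBR2 turned to -0.046 and MYC to -0.13, and with normexp and the 75th percentile SMAD4 turned to -0.031, above the median gene. In the other 8 target lists 0 genes passed over all genes tested and 0 adjusted over the list alone in limma. At an unadjusted p under 0.05 stood 2 genes each of the miR-34 list and the miR-221 and miR-222 list, 1 each of the let-7, miR-15/16 and miR-17-92 lists and 0 of the others.

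Interferon-stimulated genes report whether cells sensed the transfected RNA as foreign. TLR3, an endosomal sensor of double-stranded RNA, and SAMD9, an antiviral factor, ranked first among them, and the cytokine IL1A and the mitochondrial dismutase SOD2 among NF-kB targets. Neither list passed the threshold. The interferon list had a median of 0.033 over 42 genes (camera adjusted p = 0.0723, 30 genes higher and 12 lower, list mean higher in 3 of 5 arrays), with 0.037 and 0.024 by day. With the scan-day block its adjusted p was 0.0530, and with the composition correction as well 0.0176 (median 0.09, with 0.028 for all genes), or adjusted p = 0.894 with an estimated correlation. The inflammatory list had 0.043 over 25 genes (adjusted p = 0.143, 4 of 5 arrays; 0.090 and 0.025 by day). TLR3 stood at 0.28 ± 0.13 (adjusted p = 0.601, 5 of 5 arrays; 0.69 and 0.0055 by day), with its probe well above background on 8 arrays, and at -0.54 with normexp and the 75th percentile but 0.088 with normexp and quantile normalization. IL1A stood at 0.32 ± 0.15 (adjusted p = 0.563, 4 of 5), well above background on 5 arrays, and at -0.61 and 0.093 in these settings. SAMD9 stood at 0.11 and SOD2 at 0.12. In both lists 0 genes had an unadjusted p under 0.05 in limma, and 0 passed over all genes or adjusted over the list alone.

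Cell cycle genes ranked with CDC25A and the origin recognition subunit ORC6 first for G1/S, and the spindle checkpoint gene MAD2L1 and the mitotic kinase AURKA for G2/M. The pro-apoptotic p53 targets BAX and BBC3 led their list. The core histone genes H3C4 and H3C10 led theirs. The G1/S list had a median of 0.012 and a mean of -0.0055 over 37 genes, with the test upward (camera adjusted p = 0.425, list mean lower in 2 of 5 arrays; -0.0047 and -0.0014 by day). The G2/M list had a median of -0.0040 and a mean of 0.0019 over 44 genes, with the test upward (0.299, list mean higher in 2 of 5 arrays; -0.053 and 0.022 by day). With normexp and quantile normalization both lay below the other genes, by -0.0020 and -0.010. The histone list had -0.016 and a mean of -0.031, with the test upward (0.964, list mean lower in 2 of 5 arrays; -0.0088 and -0.027 by day), and lay above the other genes by 0.13 with normexp and the 75th percentile. ORC6 stood at -0.20 ± 0.10, MAD2L1 at 0.11 ± 0.06, AURKA at -0.14 ± 0.10 (0.011 on scan day 2), H3C4 at -0.10 ± 0.07 (0.050 after composition correction) and H3C10 at -0.17 ± 0.18 (-0.013 after it, with AURKA at -0.072). The p53 list had a median of 0.038 over 28 genes (adjusted p = 0.328, list mean higher in 2 of 5 arrays; -0.0058 and 0.034 by day). BAX had -0.40 ± 0.07 (adjusted p = 0.0982, lower in 5 of 5 arrays; -0.40 on both days), the 1 p53 target past the threshold adjusted over the list alone, with 0 over all genes and 3 at an unadjusted p under 0.05. With the scan-day block BAX passed (0.0305), its other probes gave -0.01 and -0.14, and the composition correction left -0.016. BBC3 had -0.24 ± 0.09 (0.437, 5 of 5 arrays) and 0.14 after that correction. Its probe, with 85% G and C, was far brighter (mean log2 signal 7.19) than the gene's other probes (1.48 and -1.85). These gave -0.069 and -0.16, so the level of BBC3 is uncertain. In the cell cycle and histone lists 0 genes had an unadjusted p under 0.05 in limma, and 0 passed adjusted over the list alone.

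Matrix genes make up much of a fibroblast's messenger RNA. COL6A1 and COL15A1, which encode collagen chains of the pericellular matrix, ranked first among them, N-cadherin (CDH2) and a tropomyosin (TPM2) among contractile genes, and the gelatinase MMP2 and the stromelysin MMP3 among proteases. The collagen and matrix list had a median of 0.012 over 42 genes (camera adjusted p = 0.208, 28 genes higher and 14 lower, list mean higher in 2 of 5 arrays), with -0.015 and 0.040 by day. With the scan-day block its adjusted p was 0.0887, and with the composition correction as well 0.00277 (median 0.10, with 0.028 for all genes), or adjusted p = 0.894 with an estimated correlation. The myofibroblast list had 0.037 over 22 genes (adjusted p = 0.262, 3 of 5 arrays; 0.043 and 0.029 by day). The protease list had a median of 0.0039 and a mean of -0.0026 over 16 genes, with the test upward (0.357, list mean lower in 3 of 5 arrays; -0.00081 and 0.016 by day). CDH2 stood at 0.18 ± 0.07 (adjusted p = 0.416, 5 of 5), TPM2 at -0.17 ± 0.08 (0.570, 4 of 5), COL6A1 at -0.14 ± 0.07 (0.668, 5 of 5; 0.027 with normexp and quantile normalization), COL15A1 at 0.17 ± 0.14 (0.937, 4 of 5), MMP2 at 0.13 ± 0.09 (0.852, 4 of 5) and MMP3 at -0.11 ± 0.10 (0.985, 4 of 5). After composition correction TPM2 was at -0.034 and MMP3 at -0.060. In limma 0 genes of these lists passed over all genes or adjusted over the list alone, and 1 (myofibroblast list) had an unadjusted p under 0.05.

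The machinery that makes and uses small RNAs passed with the preset correlation but not with an estimated one, with IPO8, an import factor that also binds Argonaute, AGO4, an Argonaute, DCP2, the decapping enzyme, and the RNA editor ADAR at its top. The ZNF zinc finger genes, a large family of transcription factors often predicted as microRNA targets, passed in the same way, preset correlation alone, but their top members ZNF775, ZNF496, ZNF385A and ZNF418 were lower while the family's median was higher. The silencing list had a median of 0.022 over 35 genes (camera adjusted p = 0.0428, 24 genes higher and 11 lower, list mean higher in 4 of 5 arrays), with 0.045 and 0.014 by day. It had an adjusted p = 0.264 with an estimated correlation, 0.0592 with the scan-day block and 0.0541 with the replicate block. It missed the threshold without transfected replicate 1 (0.102) or 2 (0.127) and without mock replicate 4 (0.296) or 5 (0.141). The fry test, which asks whether a list's genes move one way without setting them against others, gave an unadjusted p of 0.0197 for this list and 0.428 for the ZNF genes. The ZNF list had a median of 0.016 over 447 genes (adjusted p = 0.0381, 268 genes higher and 179 lower, list mean higher in 3 of 5 arrays), with 0.037 and 0.00068 by day. It had an adjusted p = 0.383 with an estimated correlation, 0.0530 with the scan-day block and 0.0519 with the replicate block. It too missed the threshold without transfected replicate 1 (0.102) or 2 (0.207) and without mock replicate 4 (0.296) or 5 (0.0923). In the deposited table both lists lay below the other genes, by -0.41 and -0.069. After the composition correction with the scan-day block the ZNF list's adjusted p was 0.513 and the silencing list's 0.202.

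IPO8 stood at 0.14 ± 0.05 (adjusted p = 0.363, 5 of 5 arrays), AGO4 at 0.17 ± 0.07 (0.482, 5 of 5), DCP2 at 0.13 ± 0.08 (0.786, 4 of 5; -0.023 on scan day 2) and ADAR at 0.10 ± 0.06 (0.804, 5 of 5; -0.015 as the mean of its probes). With normexp and the 75th percentile IPO8 was at -0.31, below the median gene, and AGO4 at -0.092, above it, and with normexp and quantile normalization they were at 0.11 and 0.19. ZNF775 stood at -0.37 ± 0.07 (adjusted p = 0.0982), ZNF496 at -0.42 ± 0.08 (0.0982), ZNF385A at -0.27 ± 0.05 (0.102) and ZNF418 at -0.38 ± 0.09 (0.132), each lower in 5 of 5 arrays. After composition correction DCP2 was at 0.087 and ADAR at 0.052. The 4 ZNF genes passed with the scan-day block, and after composition correction they were at -0.039, -0.25, -0.068 and -0.24. In limma without a block 0 genes passed over all genes or adjusted over the list alone in either list, with 2 silencing factors and 23 ZNF genes at an unadjusted p under 0.05. With the scan-day block 5 ZNF genes and 0 silencing factors passed over all genes. The ribosomal protein genes had a median of -0.036 over 77 genes (camera adjusted p = 0.119, 10 genes higher and 67 lower, list mean lower in 4 of 5 arrays), with -0.048 and -0.032 by day, but they lay above the other genes by 0.024 with quantile normalization, by 0.19 with normexp and the 75th percentile and by 0.030 with normexp and quantile normalization. RPL28 stood at -0.20 ± 0.08 (-0.44 and -0.035 by day) and RPL19 at -0.093 ± 0.05 (0.020 with quantile normalization), and after composition correction they were at -0.012 and -0.049. The ribosome biogenesis list, with the processome gene UTP14A (0.19 ± 0.08; 0.43 and 0.024 by day) and PPAN (-0.097 ± 0.06; 0.086 after composition correction) first, had a median of -0.013 over 30 genes (0.963, 9 genes higher and 21 lower, list mean lower in 3 of 5 arrays; -0.048 and 0.0042 by day). With normexp and the 75th percentile, and without a filter on dim probes, it lay above the other genes, by 0.16 and 0.028. Of these lists 1 ribosomal protein gene and 0 ribosome biogenesis genes had an unadjusted p under 0.05 in limma, and 0 passed adjusted over the list alone.

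Stress and metabolic programs were the remaining processes tested. The endoplasmic reticulum chaperone genes CRELD2 and DNAJB9 led the stress list, the mevalonate kinase MVK and the lipid regulator SREBF1 the cholesterol list, and JUNB and MYC the immediate early genes. BAG3 and HSP90AA1, a co-chaperone and a chaperone, led the heat shock list, and the vasodilator peptide gene ADM and the aldolase ALDOA the glycolysis and hypoxia list. The integrated stress list had a median of 0.021 over 25 genes (camera adjusted p = 0.272, 2 of 5 arrays; 0.020 and 0.040 by day). With the scan-day block its adjusted p was 0.0592, and with the composition correction as well 0.00277 (median 0.10, with 0.028 for all genes), or adjusted p = 0.894 with an estimated correlation. Leaving out 1 replicate put the list between -0.055 and 0.14 relative to the other genes. The cholesterol list had 0.016 over 26 genes (0.357, 3 of 5; 0.0055 and 0.012) but lay below the other genes by -0.0020 with quantile normalization. The immediate early list had 0.036 over 19 genes (0.157, 3 of 5; 0.028 and 0.022). The heat shock list had a median of -0.0014 and a mean of 0.011 over 12 genes, with the test upward (0.357, list mean higher in 4 of 5; -0.0071 and 0.00074). The glycolysis list had -0.0079 over 20 genes (0.990, list mean lower in 4 of 5; -0.0058 and -0.00093), and lay above the other genes by 0.15 with normexp and the 75th percentile. ALDOA stood at -0.26 ± 0.10 (adjusted p = 0.431, 5 of 5 arrays), ADM at 0.15 ± 0.06 (0.429, 5 of 5), CRELD2 at -0.18 ± 0.13 (0.861, 5 of 5), SREBF1 at -0.17 ± 0.15 (0.964, 5 of 5) and JUNB at 0.14 ± 0.08 (0.739, 4 of 5). DNAJB9 stood at 0.16, MVK at -0.10, BAG3 at 0.10 and HSP90AA1 at 0.077. After composition correction ALDOA was at 0.076, MVK at 0.018, CRELD2 at -0.0057, JUNB at 0.044, BAG3 at 0.062 and HSP90AA1 at 0.12. On scan day 2 SREBF1 was at 0.047, and as the mean of their probes JUNB was at -0.035 and HSP90AA1 at -0.0014. In limma without a block 0 genes of these lists passed over all genes or adjusted over the list alone, and 2, both of the glycolysis list, had an unadjusted p under 0.05. With the scan-day block 1 gene of the integrated stress list passed adjusted over the list alone and 0 over all genes.

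Markers of other cell types were measured to see whether signal from such cells differed between the groups. The epithelial genes SFN and KRT8, the endothelial genes EGFL7 and CLDN5, the leukocyte genes TYROBP and CD14 and the melanocyte genes PMEL and DCT ranked first in their lists. The epithelial list had a median of -0.059 over 10 measured genes of 15 (camera adjusted p = 0.451, list mean lower in 2 of 5 arrays; -0.044 and -0.029 by day), and lay above the other genes by 0.030 with normexp and the 75th percentile. The endothelial list had -0.13 over 8 of 12 (0.357, 4 of 5; -0.079 and -0.16). The leukocyte list had -0.12 over 9 of 15 (0.272, 2 of 5; -0.16 and -0.18), and after composition correction with the scan-day block it lay below the other genes by -0.011. The melanocyte list had -0.050 over 7 of 10 (0.619, 3 of 5; -0.11 and -0.072). TYROBP had -0.47 ± 0.12 (adjusted p = 0.154, 5 of 5 arrays; 0.0324 with the scan-day block), the 1 leukocyte marker past the threshold adjusted over the list alone, with 0 over all genes. CD14 had -0.26 ± 0.13 (0.608, 5 of 5; 0.0416 with the scan-day block). SFN had -0.43 ± 0.15 (0.358, 4 of 5), CLDN5 -0.66 ± 0.39 (0.775, 5 of 5), DCT -0.30 ± 0.17 (0.772, 4 of 5), EGFL7 -0.16 ± 0.07 (0.490, 5 of 5), PMEL -0.15 ± 0.08 (0.730, 4 of 5) and KRT8 -0.15 ± 0.09 (0.824, 5 of 5). After composition correction TYROBP was at -0.22, CD14 at -0.057, SFN at -0.24, CLDN5 at -0.41, DCT at -0.20, PMEL at -0.040, EGFL7 at 0.064 and KRT8 at 0.037. In the epithelial, endothelial and melanocyte lists 0 genes passed over all genes or adjusted over the list alone in limma without a block, with 1, 1 and 0 at an unadjusted p under 0.05. With the scan-day block the keratin gene KRT14 of the epithelial list passed (-0.25, adjusted p = 0.0416), and after composition correction it was at -0.070. Of the 31 lists, 2 passed with the preset correlation, 0 with an estimated one and 0 with the scan-day block (adjusted p from 0.0530 to 0.938). Within scan day 1 alone 0 lists passed. Within scan day 2 alone 8 passed upward, the interferon, G2/M, p53, collagen, myofibroblast, miR-29, miR-17-92 and integrated stress lists, and 0 with an estimated correlation (smallest adjusted p = 0.515).

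**Figure D4:**
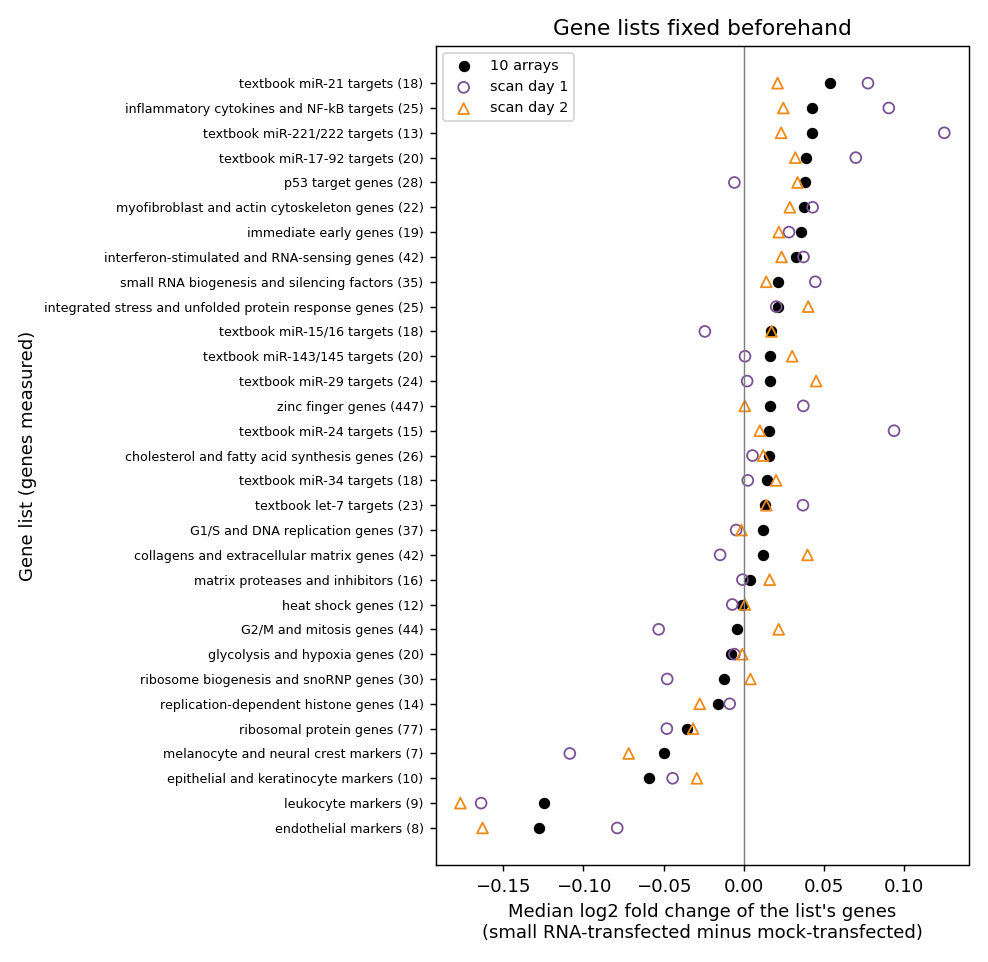
Median log2 fold change (small RNA-transfected minus mock-transfected) of each of the 31 gene lists, with the number of genes measured, over 10 arrays and within each scan day. Of the medians, 21 lie above 0 and 10 below, from 0.054 (miR-21 targets) to -0.13 (endothelial markers), and the ribosomal protein genes' position below the other genes flips with quantile normalization and with normexp.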

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

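The tests of a difference between the scan days in this part were chosen after the result was seen.

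For some genes the gap between the groups was not the same on the 2 scan days. On scan day 1 AURKA, a kinase of the mitotic spindle, SREBF1, which drives lipid synthesis, and RPL28 of the large ribosomal subunit had higher values in mock cells. On scan day 2 their values were close between the groups. The decapping enzyme DCP2 had higher values in transfected cells on scan day 1. Within scan day 1 alone 0 genes passed the threshold, so none of these was shown to differ on that day. The change of this gap between the days was tested as an interaction of group and scan day in limma. The interaction passed the threshold for 419 genes, with the effect higher on scan day 2 for 194 and lower for 225. Among the genes whose values the report gives it passed for AURKA (adjusted p = 0.016, log2 fold change -0.37 on scan day 1 and 0.011 on scan day 2), SREBF1 (0.00878, -0.50 and 0.047), RPL28 (0.0307, -0.44 and -0.035) and DCP2 (0.0319, 0.36 and -0.023). For AURKA the gap came from mock replicates 1 and 2 (3.34 and 3.37), with the other 8 arrays from 2.91 to 2.99, and for SREBF1 and RPL28 these 2 arrays were the highest as well. They had the lowest shares of probes well above background (64.2% and 65%) and the lowest 75th percentiles (944 and 984), so a property of these arrays cannot be separated from an effect of transfection here. Each gene was on its side of the mock mean in at least 4 of 5 transfected arrays. That mean pools both scan days and is raised by mock replicates 1 and 2 for AURKA, SREBF1 and RPL28. The count therefore gives no support for these genes. Some further list members under the naming rule passed as well. PBK, a kinase active in dividing cells and chosen after its values were seen, had -0.62 and 0.054 (0.00717). The G2/M list passed too (adjusted p = 0.00122, medians of -0.053 and 0.022), though not with an estimated correlation (0.933). Scan day 1 held 2 arrays per group and scan day 2 held 3, and no explanation of these differences was tested.

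Of 103 measures checked in each group of 5 arrays (named genes, list means, signal per array), 3 had 1 array apart from the rest of a group by more than 0.71 of its range, where chance gives about 1 group in 20. For ETFBKMT, a mitochondrial methyltransferase gene, transfected replicate 4 lay at -4.19 with the others from -4.07 to -4.03 (gap over range 0.717). For the RNA sensor TLR3 it was transfected replicate 2, at -4.89 with the others from -5.35 to -5.22 (0.725). For UTP14A, of the small subunit processome, it was transfected replicate 1, at -0.32 with the others from -0.56 to -0.51 (0.789).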

How the results depend on the processing

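The tests with a scan-day block, with a composition correction or within 1 scan day were chosen after seeing the data. The count of genes past the threshold in limma was 0 in each planned setting over all 10 arrays, with 365 (deposited table, 4811 genes tested) to 3476 (replicate block) at an unadjusted p under 0.05. It was 610 with scan day as a block (4324 unadjusted), and 0 with composition correction alone (1579), with it and the scan-day block (4881) or the replicate block (4001), and within scan day 1 (4758) or 2 (3199). Leaving out 1 replicate gave 0 to 383 genes. The 383, all lower, came without transfected replicate 3. The replicate block, which follows the pairing, gave 0 genes (3476 unadjusted) and 0 lists, and changed no other call than those of the silencing and ZNF lists. Normexp with the 75th percentile moved the median of all genes to -0.132 and no scaling moved it to 0.186, so single-gene values there are to be read against these.

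The number of lists past the threshold was again 2 with median, quantile, and normexp with quantile normalization, with the mean of a gene's probes and with the trend and robust prior, though the silencing list missed it with quantile (0.185) and with normexp and quantile normalization (0.140). It was 22 with normexp and the 75th percentile, 8 without scaling, 15 without a filter, 1 with each probe alone, and 0 for probes well above background on all 10 arrays (30 lists), in the deposited table (24 lists), with slide as a block or random block, with the replicate block, with scan day as a block, with composition correction, within scan day 1 and with an estimated correlation. It was 8 within scan day 2, and 3 with the correction and the scan-day block or the replicate block. Leaving out 1 replicate gave 0 to 9 lists: 0 without transfected replicate 1 or 2 or mock replicate 4 or 5, 8 and 4 without transfected replicates 3 and 4, and 9, 8 and 5 without mock replicates 1, 2 and 3. The cause was not tested for these counts or the reversals below.

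Over all settings 748 list values and 1947 values of named genes kept their direction and side of the threshold. The reversed list shifts, as the list median minus that of the other genes, and the reversed log2 fold changes of genes follow. Normexp with quantile normalization reversed G1/S -0.0020, G2/M -0.010, ribosomal proteins 0.030, COL6A1 0.027 and RPL19 0.040. Quantile normalization reversed G2/M -0.016, cholesterol -0.0020, ribosomal proteins 0.024 and RPL19 0.020. Each probe alone reversed G1/S -0.0014 and epithelial 0.0093, and the filter for all 10 arrays reversed G2/M -0.0017. Slide as a block reversed G2/M -0.0045, histones 0.0048, proteases -0.018, miR-34 -0.011, cholesterol -0.0015, heat shock -0.00041 and glycolysis 0.0029, and as a random block G2/M -0.0017, proteases -0.011 and cholesterol -0.0015. Composition correction, alone or with the scan-day block or the replicate block, reversed G2/M -0.017, histones 0.054, miR-15/16 -0.0027, miR-17-92 -0.012, ribosome biogenesis 0.025, glycolysis 0.0073, LINC00304 0.041, CHGA 0.023, H3C4 0.050, BBC3 0.14, PPAN 0.086, MVK 0.018, ALDOA 0.076, KRT8 0.037 and EGFL7 0.064.

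Normexp with the 75th percentile reversed histones 0.13, ribosome biogenesis 0.16, glycolysis 0.15, epithelial 0.030, ribosomal proteins 0.19, ETFBKMT -0.34, CDO1 -0.32, PABIR3 -0.16, GEN1 -0.34, TSPAN11 -0.073, VPS50 -0.024, TLR3 -0.54, IL1A -0.61, SMAD4 -0.031, IPO8 -0.31, AGO4 -0.092 and RPL19 0.019. No filter on dim probes reversed histones 0.025, ribosome biogenesis 0.028, glycolysis 0.033 and ribosomal proteins 0.0053. The mean of a gene's probes reversed histones 0.0078, miR-143 and miR-145 -0.0027, glycolysis 0.0021, epithelial 0.011, TGFBR2 -0.046, MYC -0.13, ADAR -0.015, JUNB -0.035, HSP90AA1 -0.0014 and KRT8 0.044. The deposited table reversed histones 0.069, silencing -0.41, glycolysis 0.096, endothelial 0.075, ZNF -0.069, PABIR3 -0.29, GEN1 -0.20 and AGO4 -0.53. No scaling reversed CDC25A 0.078, AURKA 0.051, H3C4 0.092, H3C10 0.018, COL6A1 0.052, TPM2 0.026, MMP3 0.088, MCM10 0.080, PPAN 0.097, CRELD2 0.0085, MVK 0.092, SREBF1 0.021, KRT8 0.048, EGFL7 0.034, PMEL 0.042 and RPL19 0.10, all below the shift of 0.186 of the median gene.

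Scan day 1 alone reversed G2/M -0.045, collagens -0.0069, miR-15/16 -0.016 and glycolysis 0.0021, and scan day 2 alone ribosome biogenesis 0.018, glycolysis 0.013, AURKA 0.011, DCP2 -0.023, MVK 0.0075, SREBF1 0.047 and HSP90AA1 -0.0029. Leaving out 1 replicate gave list shifts of -0.037 to 0.060 for G2/M, -0.089 to 0.090 for histones, -0.0075 to 0.062 for collagens, -0.010 to 0.059 for let-7, -0.0028 to 0.059 for miR-29, -0.022 to 0.0066 for ribosome biogenesis, -0.055 to 0.14 for integrated stress, -0.0037 to 0.051 for cholesterol, -0.022 to 0.074 for immediate early genes, -0.041 to 0.0015 for glycolysis, -0.16 to 0.025 for epithelial and -0.18 to 0.071 for melanocyte markers. Genes near background, such as IL1A (well above it on 5 arrays) and TLR3 (on 8), moved most with normexp among the genes named. The planned seed match test and its alternatives were not run, since no transcript sequences were at hand.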

Other observations

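The tests of unadjusted counts under other splits, of small nuclear and nucleolar RNA probes and of uneven probe sets in the deposited table, the correlation that fully shared changes would reach, and the correction for probe composition, were chosen after the result was seen.

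Many genes differed between the scan days. The protease inhibitor A2M, the carboxypeptidase gene CPE, the growth factor AREG and the annexin ANXA6 were higher on scan day 2, and the lectin CLEC3B, the chemokine CXCL6, the complement protease CFD, the matrix proteoglycan OGN and the homeobox gene HOXB3 were lower. As lists, stress response genes were lower with either correlation, while mitotic, p53 and collagen genes (lower) and histone and cholesterol synthesis genes (higher) passed with the preset correlation alone. In limma 13328 genes passed, 8069 higher and 5259 lower. A2M differed by 3.55 ± 0.09 (adjusted p = 1.11e-08), CPE by 2.74 ± 0.07 (1.21e-08), ANXA6 by 2.54 ± 0.05 (7.18e-09), AREG by 2.45 ± 0.05 (8.33e-09), CLEC3B by -3.17 ± 0.05 (3.88e-09), CXCL6 by -2.92 ± 0.09 (3.61e-08), CFD by -2.92 ± 0.08 (1.36e-08), HOXB3 by -2.26 ± 0.09 (1.62e-07) and OGN by -2.20 ± 0.07 (3.04e-08). Of the G2/M list 0 genes were higher and 33 lower (median -0.24, camera adjusted p = 4.62e-11), of p53 targets 3 and 19 (-0.22, 0.000133), of the integrated stress list 2 and 22 (-0.43, 1.85e-10), of collagens 9 and 26 (-0.18, 0.000148), of histones 13 and 0 (0.60, 1.71e-05), of cholesterol genes 19 and 4 (0.23, 0.0213) and of ZNF genes 102 and 141 (-0.025, 0.0398). With an estimated correlation the integrated stress list passed (0.0383), and the others did not (G2/M and histones 0.125, p53 targets 0.111, collagens and cholesterol genes 0.400, ZNF genes 0.409).

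For this difference between the scan days, an effect of hybridisation or scanning on single probes would leave separate probes of a gene unrelated, but across 6274 genes the brightest and the next probe correlated at 0.588 (genes are not independent replicates). Detector brightness as the whole cause would end with quantile normalization, after which 13065 genes passed. A different state of the cultured cells could give such a correlation, but the days of culture and of labelling are not given, so it cannot be told apart from RNA preparation or labelling.

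Genes with C-rich probes were lower in the transfected arrays in the scan-day fit. Probes of 1 gene went both ways: BAX stood at -0.40 on a probe with 28.3% C and at -0.01 on one with 15%, but COL6A1 stood at 0.02 on a probe with 33.3% C and at -0.14 on one with 18.3%, and CLDN5 at -0.66 with 31.7% C and at -1.05 with 13.3%. The CLDN5 probes were well above background on 9 and 8 arrays only, with unadjusted limma p of 0.121 and 0.0713, so their gap is uncertain. The called genes' probes had a median C content of 31.7% against 21.7% over all genes. Olfactory receptor genes, whose main site of expression is the nasal epithelium, had a median of -0.34 over 76 genes (-0.35 and -0.41 by day, -0.24 after composition correction), and 3 of them were called. They were not tested as a list. Over 31485 probes the log2 fold change went down by -0.0994 (SE 0.00141) per 10 percentage points of C. Transcript abundance as the whole cause would give no slope among probes of 1 gene, but there, over 14806 probes of 6274 genes, it was -0.0588 (SE 0.00221). Both standard errors are over probes and hold no spread between arrays. Per array, the slope of log2 signal (each probe's mean subtracted) on C content ran from -0.078 to 0.014 in transfected arrays. In mock arrays it ran from 0.017 to 0.082, with transfected replicate 3 (0.014) beside mock replicate 5 (0.017).

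Probe base composition may therefore contribute to the pattern, since the slope of -0.0588 held within genes. The correction took the called genes' median from -0.39 (median SE 0.0675) to -0.19 (0.0608), and 0 of the 610 remained past the threshold. Some lost the call with values about as large (DCANP1 from -0.73 to -0.70) or larger (SLC6A9 from 0.26 to 0.38), and why was not tested. A difference between slides stays open. On slide 1 the transfected array's slope lay -0.125 below the lower mock array (mock SD 0.00217), on slide 3 by -0.00281 (mock SD 0.0331), and slides 2 and 4 held transfected arrays alone, so for these slides slide and group cannot be told apart. Of 60 splits that keep the scan days, 1, the real one, gave 610 genes or more, with 1 as the highest other count. The scan-day fit was itself chosen after seeing the data, so this count does not exclude chance. A slide effect is not excluded either. At an unadjusted p under 0.05 the real split gave 4324 genes and the highest other nearly as many, 4245.

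For the comparison without a block, all 100 splits drawn of 126 gave at least its 0 genes, as any split must, so this count decides nothing about chance. The highest other split gave 8718. That split put all 4 arrays of scan day 1 on 1 side, which points to the scan-day structure of the samples. With scan day as a block the real split gave 610. For the 2097 genes at an unadjusted p under 0.05, 11 of the 100 splits gave as many, up to 11499 genes, so chance cannot be excluded. The 16 splits that part every pair, the real one among them, are too few for a share under 0.05, with 2097 genes against 1776 as the highest other.

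A change in messenger RNA would appear on several probes of a gene, as for SAMD9 and VPS50, whose 4 probes each were all positive, while those of BAX and BCL2 differed (the second BCL2 probe is well above background on 7 arrays). Of 47 genes under the naming rule with several probes, 19 had probes that differed in sign. Across 6274 genes the blocked and corrected log2 fold changes of the brightest and the next probe correlated at 0.187, and at 0.296 before the composition correction, against 0.588 for the scan days. Noise lowers such a correlation, and changes shared in full would reach 0.525 at the standard errors of this fit (0.948 for the scan days). A partly shared change stays open. Transfected small RNA read by the arrays could raise the probes of small nuclear and nucleolar RNAs, if the labelling takes up such RNAs. The 7 such genes measured had medians of 0.016 and 0.033 by day after correction, with 0 past the threshold and 0 at an unadjusted p under 0.05 in limma. Whether the labelling takes them up was not tested, so these 7 genes cannot exclude that transfected RNA was read.

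Averaging over the probes detected on each array may add spread to the deposited table. Genes whose averaged probes differed between arrays (1213) had a median SD of 0.705 over the arrays, against 0.301 for the 723 with a constant set, a ratio of 2.35. Most of its 1534 missing values fell on mock replicates 1 (784) and 2 (652). In that table PABIR3 stood at -0.29, GEN1 at -0.20 and AGO4 at -0.53, each opposite in sign to the scanner values. No biological explanation of this was tested.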
